A study of Saccharomyces cerevisiae with 15 samples.

How the data were processed

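Total RNA of Saccharomyces cerevisiae BY4741 grown in YPD was labelled with Cy3 and genomic DNA with Cy5, and both were hybridised to Agilent arrays, per the labels. The dyes were not swapped, so dye and molecule cannot be separated. Of 15 samples, the 2 arrays were analysed. The 13 sequencing libraries were not analysed here. Both arrays lay on 1 slide and were scanned together, per the file headers.

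Spot intensities were extracted with Agilent Feature Extraction 10.5.1.1, per the submitters' processing notes. The values used are spot intensity values after subtraction of a fitted spatial background, which can be negative, per the file headers. The multiplicative detrend signal, a fitted surface of intensity gradients across the slide, is given per spot, per the file headers. The processed intensity equalled the background-subtracted intensity divided by that surface, as tested on every spot of the RNA channel. No dye normalization was recorded, per the file headers, although one had been assumed when the choice of signals was fixed. Signals called gradient-corrected are these processed intensities. No genome build is given in the sources used here, so no coordinates are printed. Systematic names were matched to locus tags of RefSeq assembly GCF_000146045.2 (R64, S288C): 5756 of 6256 matched and 500 did not and kept the name in the files.

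A spot was kept when its DNA signal was well above background and neither channel was saturated or a non-uniformity outlier, on both arrays. This kept 43721 of 43792 gene spots and 6250 genes, 6221 of them with all 7 spots. No spot was saturated. RNA intensities under 3 SD of the 153 negative control spots of an array were raised to that floor (17.05 and 32.9). The ratio of a gene is the median of log2(RNA/DNA) over its spots, minus the median over genes on that array. Each value is the mean of 2 arrays with its SD. A gene with RNA at the floor on either array is given as an upper bound. The median spot-to-spot SD of the log2 ratio was 0.20 on array 1 and 0.12 on array 2.

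Genes were tested against the median gene with limma 3.58.1 in R 4.3.3 (intercept only, empirical Bayes without trend, Benjamini-Hochberg adjustment) and called at an adjusted p under 0.05 and an absolute log2 value of at least 1. Lists were tested with limma's camera (two-sided, preset correlation 0.01) over the 24 of 25 lists with at least 3 measured genes. The list of marker genes had none, since all 4 lacked DNA signal. One symbol of the amino acid list was not found on the arrays. Other values were computed in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots with matplotlib 3.10.9. The tests were tried on simulated data for the comparison with the median gene, over 6250 genes of which 200 were shifted. Of 50 genes per size, 2% were called at a log2 shift of 0.75, 96% at 1.25, 96% at 1.5 and 98% at 2. Of the 6050 unshifted genes, 0.0165% were called. The planted list was found and 0 of 24 null lists passed. Noise was drawn independently per gene, so camera was not tried on lists of correlated genes. In the data, 5896 genes had an adjusted p under 0.05, far more than the 200 shifted here.

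The tests, the lists and the rule for named genes were fixed before the data were examined. Named were the 10 highest and 10 lowest called genes on the same side of the median on both arrays, up to 2 highest and 2 lowest members of each list, all marker, a-cell, alpha-cell and galactose genes, and ACT1, TUB1 and ADH1. Alternatives changed the signal, background subtraction, normalization, spot summary, spot filter, floor, reference channel, thresholds, test and arrays used. The robust floor, chosen after seeing the data, is the median plus 3 robust SD (from the median absolute deviation) of the negative control spots.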

Results

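The series compared 11 strand-specific and 2 control RNA sequencing libraries of budding yeast with reference expression levels from 2 two-colour arrays. The 13 sequencing libraries were not analysed here, so no comparison between library methods is made. On each array, Cy3-labelled total RNA of BY4741, a haploid laboratory strain of mating type a that lacks several biosynthetic genes, was hybridised together with Cy5-labelled genomic DNA. YPD, the medium named for these samples, is a rich medium with glucose. The RNA/DNA ratio of a gene is thus its RNA signal set against the DNA signal at the same probe. Across genes, the mean log2 DNA signal rose with the mean log2 RNA signal (Pearson r = 0.38). The DNA signal thus cannot be read as gene copies alone, and the cause was not tested. The arrays carried 6256 genes, each with 1 probe printed as 7 spots. The median gene had an RNA intensity of 1135 on array 1 and 1390 on array 2, against floors of 17.05 and 32.9 set from the negative control spots. The median DNA intensities were 4184 and 4558. The number of arrays, 2, limits the precision of every value. The labels do not say that the arrays came from separate cultures, and both lay on 1 slide. The limma p-values of single genes thus measure only the spread between these arrays, which may be technical. The camera and permutation p-values for sets of genes rest on the spread across genes, which are not replicates.

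The first comparison asks how repeatable the reference measurement was. Across 6250 genes, log2(RNA/DNA) of the arrays had a Pearson r of 0.998 and a Spearman rho of 0.999, as a description, since genes are not independent replicates. RNA alone gave an r of 0.998 and DNA alone 0.994. No gene differed by 1 or more on the log2 scale, and 93.3% differed by less than 0.5. With RNA above the floor on both arrays, 99.9% differed by less than 0.5. For the 446 genes at the floor on both arrays, the floors and the DNA signal set the difference. Their RNA was not compared by it. The SD of the difference was 0.20 over all genes and 0.10 over the 5702 genes whose RNA lay above the floor on both arrays. Among 5187 genes with RNA intensities above 200 on both arrays, 5.90% differed between arrays by more than the spread of their own spots at p under 0.05 in an F test per gene, where chance gives 5%. With signals corrected for intensity gradients across the slide, the share was 18.5%. This test cannot show whether the arrays held separate RNA samples or 1 sample hybridised again, and they were counted as 2 samples as labelled.

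**Figure D1:**
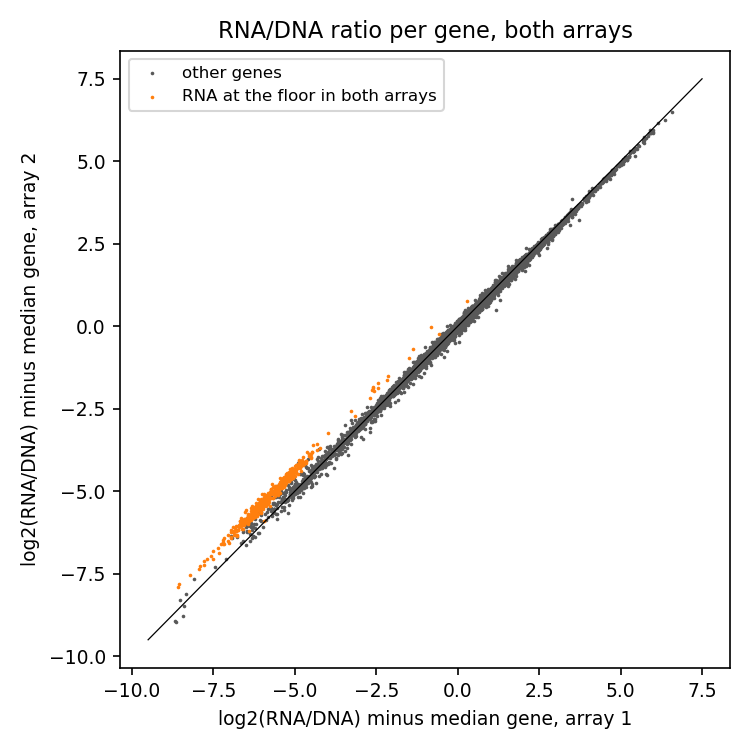
Log2(RNA/DNA) per gene relative to the median gene on array 1 (x axis) and array 2 (y axis), 1 point per gene, with the line of equality. Pearson r was 0.998 over 6250 genes; the 446 genes with RNA at the floor on both arrays (orange) lie mostly above the line, where the floors of 17.05 and 32.9 set the ratio.

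The marker genes of BY4741 stood apart in the DNA channel. HIS3 (YOR202W), LEU2 (YCL018W), MET17 (YLR303W) and URA3 (YEL021W), the biosynthetic genes deleted in whole or in part in BY4741, had almost no DNA signal. The labels name the DNA as BY4741 in one field and tag its strain as progenitor in another. The near absence of DNA signal at all 4 markers argues against DNA from a strain that carries these genes. What the progenitor tag means was not resolved. Their DNA intensities ran from -3.11 for HIS3 to 3.56 for URA3 on array 1, and from -2.35 to 7.39 for the same genes on array 2. The highest of these values was 0.0851% of the median gene's DNA signal on array 1 and 0.162% on array 2. Of all genes, 6 had no spot with usable DNA signal, and 4 of them were these markers. The others were YLR302C, numbered next to MET17, and YDR544C, both singled out after their values were seen. RNA at the 4 markers was under the floor on both arrays, with 17.9 for LEU2 on array 2 as the highest intensity. The lowest DNA intensity among the genes kept was 37.6 on array 1 and 37.7 on array 2.

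**Figure D2:**
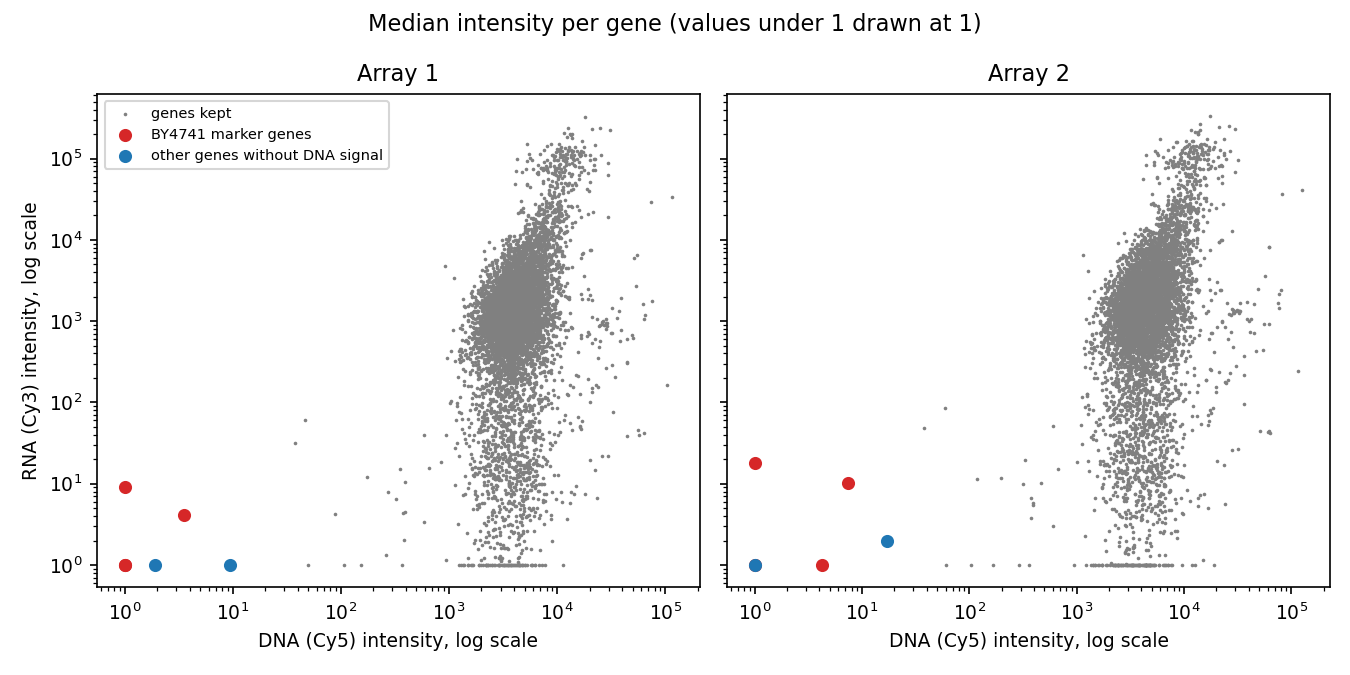
Median RNA (Cy3) against DNA (Cy5) intensity per gene on array 1 (left) and array 2 (right), both axes on a log scale, with values under 1 drawn at 1. The 4 BY4741 marker genes (red) and 2 further genes (blue) lie below all kept genes in DNA intensity.

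RNA was detected for most genes. It lay above the floor on both arrays for 5702 of 6250 genes, or 91.2%, and for 92.9% on array 1 and 91.2% on array 2 taken singly. RNA of 446 genes was at the floor on both arrays, and of 548 on at least 1, so their ratios are upper bounds.

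Genes of ribosomal proteins made up 8 of the 10 highest RNA/DNA ratios, and TDH3 and CCW12 the others. Relative to the median gene, 1760 genes lay above and 1952 below by at least 1 on the log2 scale at an adjusted p under 0.05 in limma, and 2538 were not called. Of the 1952 below, 1407 had RNA above the floor on both arrays. Another 443 had RNA at the floor on both, where the floors and the DNA signal set the spread between arrays. RPL29 (YFR032C-A), a protein of the large ribosomal subunit, was highest at 6.54 ± 0.05 (SD, n = 2). RPL37A (YLR185W) followed at 6.30 ± 0.09, RPL41A (YDL184C) at 6.16 ± 0.01, and TDH3 (YGR192C), the main glyceraldehyde-3-phosphate dehydrogenase, at 5.98 ± 0.03. The rest of the 10 highest were RPS31, RPL41B, CCW12, RPL32, RPL25 and RPS17A, between 5.89 and 5.95. CCW12 encodes an abundant cell wall mannoprotein. RPL37A, RPL41A, RPL41B, RPS17A and TDH3 have near-identical copies, so signal at their probes may be shared. ADH1, the main alcohol dehydrogenase of fermentation, stood at 5.08 ± 0.04, ACT1 (actin) at 3.89 ± 0.15 and TUB1 (alpha-tubulin) at 1.35 ± 0.04.

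With the floor of 3 SD, the 10 genes with the lowest printed ratios had a high DNA signal. Picking them for a low ratio itself selects a high DNA signal, because their RNA lay at or near the floor. Genes with RNA at the floor have no measured rank, since their ratios are upper bounds: DAN1, at most -5.58 here, was at most -9.56 with the robust floor. Among the genes measured above the floor on both arrays, YAL069W was at -8.80 ± 0.21, Q0017 at -8.79 ± 0.19, YHR217C at -8.61 ± 0.23 and YDR543C at -8.44 ± 0.07. YJR162C, YNR077C and YAR061W, with RNA under the floor on array 2, had ratios of at most -8.41, -8.23 and -7.87. RNA of YIL175W, Q0182 and HSP33 was at the floor on both arrays, with ratios of at most -8.24, -8.19 and -7.89. All 10 had a DNA signal at or above percentile 98.5 of the genes, and their probes may detect several similar sequences. With the RNA channel alone, YAL069W was at -4.95 and Q0017 at -4.86. Limits: with the log2 threshold at 2, 774 genes were above and 1278 below, and with the adjusted p alone 2944 and 2952. With the RNA channel alone, 1805 genes were above and 1868 below, close to the main counts. The genes called differed more: 1492 of those above and 1656 of those below were also called by RNA/DNA, among 1760 and 1952.

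The lists of genes for growth lay above the other genes. All 137 cytosolic ribosomal protein genes were above the median gene, with a list median of 4.82 and a lowest member, RPL15B, at 1.03 ± 0.04. RPL15B fell short of the threshold with gradient-corrected signals, at 0.95, and at 0.83 without genes at the floor, which lowered all ratios by moving the median gene (a shift of -0.19). Of 29 translation initiation and elongation factors, 28 were above and 1 was not called, with EFB1 at 5.27 ± 0.04 and TEF1, which has a near-identical copy, at 4.96 ± 0.08. TIF4632 was at 0.33 ± 0.03. Of 82 ribosome biogenesis genes, 65 were above and 17 not called, with a median of 1.58. NOP56, of the box C/D particles that modify ribosomal RNA, was at 3.51 ± 0.11 and NOP10 at 3.36 ± 0.01. SSF1 was at -0.07 ± 0.07, and at 1.27 with the RNA channel alone. All 8 core histone genes were above, from HTA2 at 3.40 ± 0.02 to HTB1 at 4.05 ± 0.02. Core histone genes and many ribosomal protein genes have similar copies, so signal at their probes may be shared. The median DNA percentile was 95.1 for the histones and 94.5 for the ribosomal proteins. All 32 proteasome genes were above, with a median of 1.91, from PUP3 at 1.06 ± 0.02 (0.87 without genes at the floor) to RPN3 at 2.77 ± 0.02. In the camera test against all other genes, with a preset correlation of 0.01, the adjusted p was 5.93e-22 for ribosomal proteins, 9.01e-08 for translation factors, 2.99e-11 for ribosome biogenesis, 0.000996 for histones and 1.3e-07 for the proteasome. For each of these 5 lists it was an adjusted p = 0.448 with an estimated correlation, which rests on 1 residual degree of freedom.

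**Figure D3:**
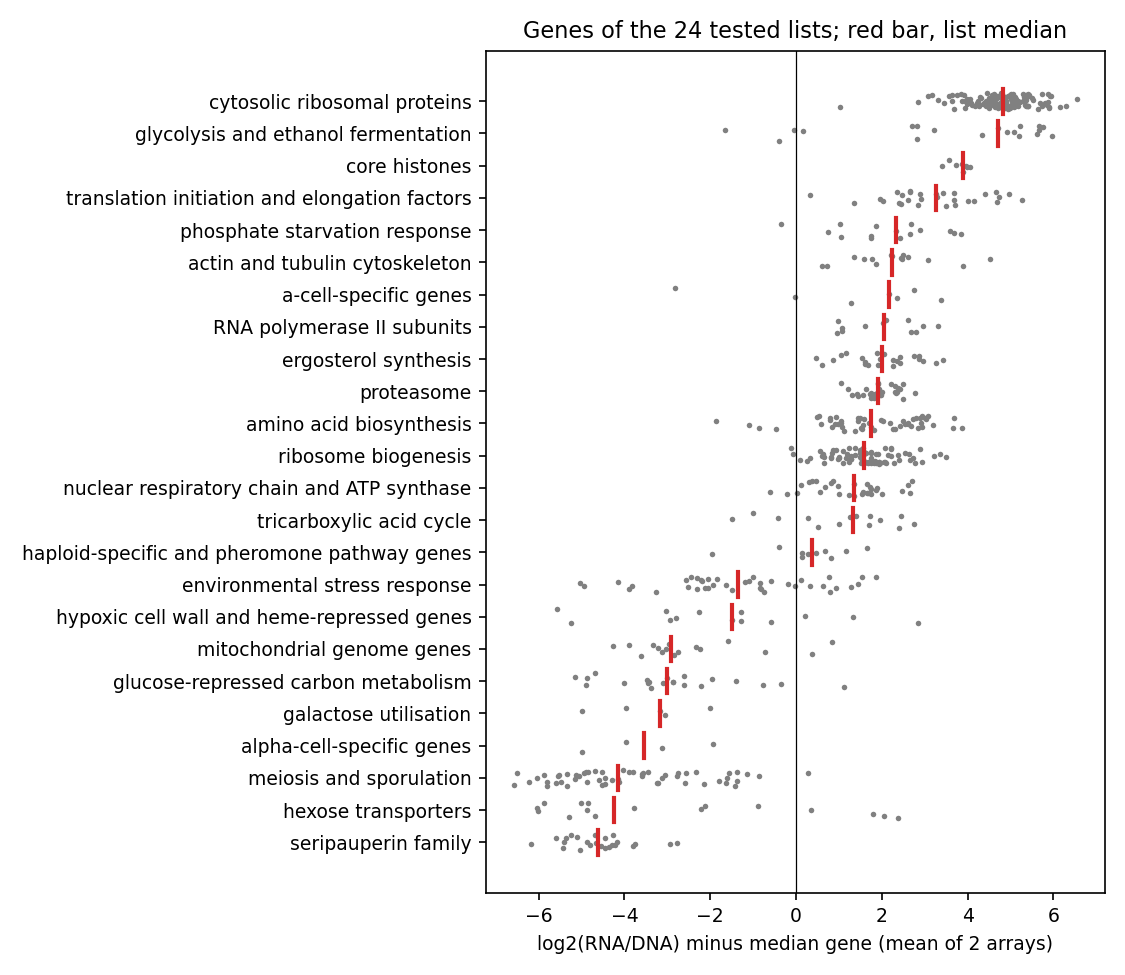
Log2(RNA/DNA) relative to the median gene, mean of 2 arrays (x axis), for each measured gene (grey) of the 24 tested lists (y axis), with the list median in red. Medians run from -4.60 for the seripauperin family to 4.82 for cytosolic ribosomal proteins; genes with RNA at the floor are drawn at their upper bound.

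Glycolytic genes were high and respiratory genes moderately so. Of 19 genes of glycolysis and ethanol fermentation, 15 were above and 1 below, with a median of 4.70. GPM1, phosphoglycerate mutase, was at 5.75 ± 0.05. HXK1, a hexokinase repressed by glucose, was below at -1.66 ± 0.04, and TDH1 was at -0.40 ± 0.04. Of 14 tricarboxylic acid cycle genes, 9 were above and 1 below, with MDH1 at 2.74 ± 0.02, ACO1 at 2.44 ± 0.06 and SDH2, a subunit of succinate dehydrogenase, below at -1.49 ± 0.08. SDH1, of the same enzyme, was at -0.996 ± 0.07 and not called, but was called below under 4 settings, at -1.03 with gradient-corrected signals, -1.06 with the mean over spots, and -1.19 both with the RNA channel alone and without genes at the floor. Of 31 nuclear genes of the respiratory chain and ATP synthase, 19 were above and 12 not called, with ATP2 at 2.71 ± 0.05 and CYT1 at -0.61 ± 0.06. The camera adjusted p was 0.000522 for glycolysis, 0.0343 for the tricarboxylic acid cycle and 3.98e-05 for the respiratory chain. It became an adjusted p = 0.541 with an estimated correlation for the tricarboxylic acid cycle and 0.448 for the others, and 0.0509 for the tricarboxylic acid cycle without genes at the floor.

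Genes of alternative carbon sources were low. Of 21 glucose-repressed genes, 18 were below and 1 above, with a median of -3.00. POX1, of fatty acid oxidation, was at most -5.14, ADY2, an acetate transporter, at -4.89 ± 0.05, and ACS1 was not called at -0.35 ± 0.02, but was called below with the RNA channel alone, at -1.21. SUC2, invertase, was above at 1.13 ± 0.01 and under the threshold with the RNA channel alone, at 0.60, and without genes at the floor, at 0.94. All 5 galactose genes were below, with GAL1 at -2.002 ± 0.03, GAL10 at -3.04 ± 0.00, GAL3 at -3.16 ± 0.27, GAL2 at -3.96 ± 0.13 and GAL7 at -4.99 ± 0.05. Among 16 hexose transporters, 11 were below and 3 above, with HXT2 at 2.39 ± 0.01 and HXT1 at 2.06 ± 0.01. HXT17 was at -6.02 ± 0.08 and HXT9, with RNA under the floor on array 2, at most -6.04, both in families of similar copies. The camera adjusted p was 3.57e-05 for glucose-repressed genes, 0.0142 for galactose genes and 0.0493 for hexose transporters. For each of the 3 lists it was an adjusted p = 0.448 with an estimated correlation. The hexose transporter call ended under 5 settings, with an adjusted p of 0.0509 with gradient-corrected signals, 0.0541 with the mean over spots, 0.0522 without the spot filter, 0.0694 on ranks and 0.491 without genes at the floor. The list median, -4.23, was -4.20 with gradient-corrected signals, -4.175 with the mean over spots and -4.23 without the spot filter. Without genes at the floor it was -1.07.

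Most a-cell-specific genes lay above the median gene and all alpha-cell-specific genes below it. Of 7 a-cell-specific genes, 5 were above. The a-factor genes MFA2 and MFA1 were at 3.39 ± 0.03 and 2.74 ± 0.05, the alpha-factor receptor STE2 at 2.35 ± 0.05, the protease BAR1 at 2.17 ± 0.03 and the a-factor exporter STE6 at 1.30 ± 0.02. ASG7 was below at -2.82 ± 0.05. AGA2, an agglutinin subunit, was at -0.03 ± 0.03, at 0.0146 with gradient-corrected signals and at 0.51 with the RNA channel alone. All 4 alpha-cell-specific genes were below, with SAG1 at -1.94 ± 0.11, STE3, the a-factor receptor, at -3.12 ± 0.10, MF(ALPHA)2 at -4.99 ± 0.10 and MF(ALPHA)1 at most -3.96. The mean of the a-cell genes was at least 4.80 higher than that of the alpha-cell genes, with MF(ALPHA)1 at its bound (exact two-sided permutation test over genes, which are not replicates, p = 0.0121). Against all other genes the a-cell list was not called in camera, with an adjusted p of 0.107 (0.0464 with the RNA channel alone and 0.0454 on ranks). The alpha-cell list was called with 0.0345, and 0.0511 under quantile normalization. Both gave an adjusted p = 0.448 with an estimated correlation. Of 10 haploid-specific and pheromone pathway genes, 2 were above (STE18 at 1.65 ± 0.06 and GPA1 at 1.18 ± 0.02, or 0.98 without genes at the floor) and 1 below (FUS1 at -1.96 ± 0.03), and AXL1 was at -0.40 ± 0.01. That list had a camera adjusted p of 0.16.

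The amino acid, ergosterol, phosphate starvation, cytoskeleton and RNA polymerase II lists lay above the other genes. Of 53 amino acid biosynthesis genes, 40 were above and 2 below, with ILV5 at 3.87 ± 0.01 and BAT1 at 3.68 ± 0.05, both of branched-chain amino acid synthesis, and ARG3 at -1.86 ± 0.05 and MET2 at -1.08 ± 0.08. Of 24 ergosterol synthesis genes, 21 were above, with ERG11, the azole drug target, at 3.44 ± 0.10 and ERG20 at 3.26 ± 0.29. ERG12 and HMG2 were not called, at 0.47 ± 0.01 and 0.60 ± 0.05. Of 15 phosphate starvation genes, 13 were above, with SPL2 at 3.85 ± 0.12 and PHO84, the high-affinity phosphate transporter, at 3.68 ± 0.06. PHM6 was at 0.75 ± 0.05 and PHM8 at -0.36 ± 0.03, and with the RNA channel alone both were called, at 1.14 and -1.90. Of 15 actin and tubulin cytoskeleton genes, 13 were above, with COF1, cofilin, at 4.53 ± 0.05. TUB3 and SAC6 were not called, at 0.71 ± 0.00 and 0.62 ± 0.00, but were called above with the RNA channel alone, at 2.12 and 2.11. Of 12 RNA polymerase II subunits, 10 were above, with RPC10 at 3.31 ± 0.06 and RPB5 at 2.97 ± 0.01, which also belong to the other nuclear RNA polymerases. RPB11 and RPB7 were not called, at 0.99 ± 0.12 and 0.95 ± 0.03, but were called above with the RNA channel alone, at 1.81 and 1.484, and RPB7 with gradient-corrected signals, at 1.01. The camera adjusted p was 9.01e-08 for amino acids, 3.28e-06 for ergosterol, 0.000522 for phosphate, 9.84e-05 for the cytoskeleton and 0.000514 for the polymerase. Each was an adjusted p = 0.448 with an estimated correlation.

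Meiotic, stress and hypoxic genes were mostly low. Of 56 meiosis and sporulation genes, 54 were below, and 14 had RNA at the floor on both arrays. MER1, a meiotic splicing regulator, was at most -6.57 and LDS2 at most -6.51. MSH5 and SPR6 were not called, at -0.87 ± 0.04 and 0.29 ± 0.01, but MSH5 was called below with the RNA channel alone, at -1.10, and without genes at the floor, at -1.06. All 24 seripauperin genes, a subtelomeric family of similar copies whose probes may share signal, were below, with a median of -4.60, from PAU10 at -6.17 ± 0.08 to PAU17 at -2.78 ± 0.04. Their median was -3.19 with the RNA channel alone (camera adjusted p of 3.36e-07). Their median DNA percentile was 94.5, and a high DNA signal lowers the ratio. Of 40 stress response genes, 23 were below and 4 above, with DDR2 at -5.03 ± 0.00 and GND2 at -4.94 ± 0.09. HOR7 and the disaggregase HSP104 were above at 1.86 ± 0.10 and 1.54 ± 0.08. Of 13 hypoxic genes, 9 were below and 2 above, with DAN1 at most -5.58, TIR2 above at 2.85 ± 0.05 and HEM13, of heme synthesis, above at 1.34 ± 0.04, or 0.89 with the RNA channel alone. Of 16 genes of the mitochondrial genome, 13 were below, with VAR1 at -4.26 ± 0.36 and COB at -3.89 ± 0.00, or -1.23 with the RNA channel alone. The median of this list was -2.91, and -1.97 with the RNA channel alone (camera adjusted p of 0.0136). The DNA signal of the mitochondrial entries lay 0.72 above the median of all genes on the log2 scale, which lowers their ratios. OLI1 was not called at 0.84 ± 0.47, with 1.18 on array 1 and 0.51 on array 2, but was called above with the RNA channel alone, at 3.63. The camera adjusted p was 4.95e-10 for meiosis, 1.03e-07 for seripauperins, 0.00369 for stress, 0.0345 for hypoxia and 0.00164 for the mitochondrial genome. Each was an adjusted p = 0.448 with an estimated correlation. The counts adjusted over the list alone were identical to those over all genes in all 24 tested lists. The strand comparison was not run, because each gene had 1 probe and the files annotate no second strand.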

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

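The spike-in control spots, which no comparison used, carried a strong signal in the RNA channel. The brightest of 10 spike-in probes had a median RNA-channel intensity of 54716 on array 1 and 89490 on array 2, against floors from the negative control spots of 17.05 and 32.9. The spike-in probes were 1.76 times as bright on array 2 as on array 1, and yeast genes in the same intensity range 1.22 times.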

How the results depend on the processing

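The higher floor, the robust floor, leaving out genes at the floor, and single arrays for the marker genes were chosen after seeing the data. Gene counts stayed within 1.5 times the main 1760 above and 1952 below, except on changed thresholds. A log2 threshold of 2 gave 774 and 1278, and the adjusted p alone 2944 and 2952. The RNA channel alone kept 1492 and 1656 main calls. Size alone on 1 array gave 1756 to 1763 above and 1935 to 1956 below. Of 13 lists above and 9 below, 0 and 0 held with an estimated correlation (adjusted p from 0.448 to 0.541), which has 1 residual degree of freedom.

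The Pearson r of the arrays, 0.9980, left its bootstrap interval over genes with gradient-corrected signals (0.9981), no background subtraction (0.9990), quantile normalization (0.9985), a floor of 1 SD (0.9985), the higher floor on both arrays (0.9988), the robust floor (0.9966) and without genes at the floor (0.9988); the cause was not tested. The share of genes with RNA detected, 91.2%, was 94.8% with a floor of 1 SD, 97.9% with the robust floor and 92.7% by the Feature Extraction flag, and 91.2% to 92.9% on a single array; a lower floor admits more genes by construction. The highest marker DNA signal, 0.124% of the median gene, was 1.83% without background subtraction, which leaves the background in, and 0.0851% to 0.162% on a single array. AGA2, at -0.03 and not called, was at 0.0146 with gradient-corrected signals and 0.51 with the RNA channel alone. SSF1, at -0.07 and not called, was at 1.27 with the RNA channel alone. That setting leaves out the DNA signal by construction, which lay at percentile 69.9 for AGA2 and 93.9 for SSF1. The cause of the change in AGA2 with gradient-corrected signals was not tested.

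Over 10 alternatives of signal, summary, filter, floor, normalization, reference channel and genes kept, the 22 called lists kept call and direction in 214 of 220 comparisons and lost the call in 6, and the 2 lists not called gained one in 1 of 20. On ranks 1 list lost its call and 1 gained it, and with an estimated correlation all 22 called lists lost it. Over the same 10 alternatives, the 97 called named genes kept call and direction in 951 of 958 comparisons and lost the call in 7, and the 22 not called gained one in 17 of 220, SSF1 included. With the RNA channel alone, 37 of 119 named genes moved by over 1.5 times, which removes the DNA signal from the ratio; among them TEF1 was at 7.61, ILV5 at 5.94, TIR2 at 5.70, TUB1 at 2.75, PUP3 at 2.46, STE6 at 2.27 and HXK1 at -1.06. Among named genes, limma's treat ended 3 calls (MET2, PUP3 and RPL15B), a log2 threshold of 2 ended 18, the adjusted p alone added 19 and the intensity trend changed 0. Camera and the correlation of the arrays have no value on a single array, which leaves no residual degree of freedom and no second array. Detection does not depend on quantile normalization or, apart from the spot filter, on the DNA channel. Leaving out genes at the floor fixes detection at its maximum. None of these settings was run for detection. No paired analysis was possible because only 1 group has arrays. The signal over background limits low genes: 446 had RNA at the floor on both arrays.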

Other observations

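The tests on the lowest ratios and on missing DNA were chosen after the results were seen, and the comparison with open reading frames outside the RefSeq table was also added then, as was the rule that the whole interval of a difference had to pass its bound. Of the measured open reading frames, 499 had no entry in the RefSeq table of assembly R64. Their median log2(RNA/DNA) was at most -5.04, since RNA of 266 of them was at the floor on both arrays, against 0.16 for the 5751 genes in the table (two-sided permutation test over genes, p = 1e-05, the smallest that 100000 permutations can give). RNA lay above the floor on both arrays for 38.3% of them and for 95.8% of the genes in the table.

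The median DNA signal per nuclear chromosome, by the letter in the systematic name, lay between -0.09 (H) and 0.17 (E) of the median of all genes on the log2 scale. The 23 mitochondrial entries lay 0.72 above it.

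DNA signal was low at several open reading frames outside the table that are numbered beside an abundant gene of the opposite strand, all singled out after their values were seen. YGL102C, beside RPL28, had DNA intensities of 49.2 and 60.0, and YKL153W, beside GPM1, 263.1 and 287.9. Of the 20 lowest, 19 had an opposite-strand neighbour, and 14 of those neighbours were in the top 5% of ratios. The neighbours' median DNA percentile was 94.1. This cannot exclude DNA missing from the strain at the reading frames themselves. The neighbours were matched by number and picked for a high ratio among genes with usable DNA signal. A candidate explanation is that abundant labelled cDNA binds the matching DNA strand in solution.

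With those 20 left out, DNA signal fell with the neighbour's ratio (Spearman rho = -0.29 across 352 reading frames, permutation p = 1e-05, the smallest possible), as that explanation predicts. Same-strand neighbours, for which it predicts no such relation, also gave a rho of -0.17 (235 reading frames, permutation p = 0.00734), and the difference between both was not tested. In 30 overlapping opposite-strand pairs of annotated genes rho was 0.10 (permutation p = 0.616), opposite in sign to what the explanation predicts. Those pairs were taken by gene overlap, without checking that the probe lay in the overlap. The member with the lower ratio was used, which favours a high DNA signal, so the pairs cannot decide. Weak probes in general cannot be told apart from it: reading frames with an abundant neighbour were 0.56 lower (difference -0.56, bootstrap interval -0.89 to -0.09, 13 against 339, permutation p = 0.0238). That goes against equal signal in both sets, but the interval runs past the bound of 0.5 set for excluding weak probes. No biological explanation was tested.

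The 10 lowest ratios had a median DNA percentile of 99.4, and RNA was at the floor on both arrays for 3 of the 10. Several genomic copies and RNA at background cannot be told apart as causes, because genes picked for a low ratio with RNA near the floor have a high DNA signal by that choice. No biological explanation was tested.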
